A study of Mus musculus with 7 samples.

How the data were processed

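Single-cell RNA sequencing was deposited for 7 mouse libraries made with droplet-based capture of transcript ends. They held dissociated blastocysts (day 0, 1 library), blastocyst outgrowths grown for 8 days on feeder fibroblasts (1 library), an embryonic stem cell line (ESC), a trophoblast stem cell line (TSC) and an extra-embryonic endoderm cell line (XEN) each grown alone (1 library each), and all 3 lines grown together for 5 days (2 libraries, replicates 1 and 2). The lines and the outgrowth were kept in the same medium, which the labels call FTW. Per the labels, blastocysts were digested far longer than the lines before capture. The authors deposited raw unique molecular identifier (UMI) counts per gene and cell barcode for each library, and the deposited values carry no scaling or normalization. The other deposited files of each library hold text only, the barcodes and the gene identifiers of the matrix. Per the file headers the matrices came from Cell Ranger 6.0.0, and per the labels the genome build was mm10 (GRCm38). The annotation release and alignment settings are not given in the sources used here. Every matrix held 32285 genes, and gene positions were taken from an mm10 annotation.

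Barcodes with at least 1000 detected genes and at most 15% mitochondrial counts were kept. Doublets were scored against simulated cell pairs by the share of simulated pairs among the 50 nearest neighbours. The barcodes with the highest scores were removed up to 0.8% per 1000 barcodes recovered, except in libraries under 500 cells. The 5 culture libraries were clustered together, the blastocyst and the outgrowth alone. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were standardized and clipped at 10 SD, and Leiden clustering ran on the neighbour graph of the principal components. Components, neighbours and resolution were 30, 20 and 1.0 for the cultures, 10, 10 and 1.0 for the blastocyst, and 30, 20 and 0.35 for the outgrowth. Clusters were named from fixed marker lists and their 10 leading genes with at least 20 CPM (gene UMIs as a fraction of all UMIs of the sum, on the usual CPM scale). Clusters led by markers of several classes, of none, or of a derived state were kept apart and reported by number. Blastocyst cluster 1 departs from that rule: it was named epiblast-like although its 10 leading genes held 1 epiblast and 1 primitive endoderm marker. Some other named clusters also held 1 leading marker of another class beside more of their own. Among them was blastocyst cluster 2, named trophectoderm-like, with 2 trophectoderm markers and the primitive endoderm marker Lrp2.

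UMI counts of the cells of a class were summed per library. Co-cultured and monocultured cells of the ESC-like, TSC-like and XEN-like classes were compared with the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, two-sided, TMM scaling, filterByExpr) on 3 sums per class, which leaves 1 residual degree of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, and "rose" or "fell" marks an adjusted p under 0.05. Gene lists are also given adjusted over the list alone. A list's median fold change was placed among 10000 random lists drawn from the 100 genes nearest each member in expression, as a percentile. A called gene was marked partner-enriched when its monoculture CPM in a partner line exceeded 2 times that in its own line. Differences between classes were tested in 1 fit of all 9 sums. In a check on simulated counts with 200 changed genes per class, the test recovered 81.0%, 83.5% and 77.0% of 2-fold changes in ESC-like, TSC-like and XEN-like cells at adjusted p under 0.05, and 47.5%, 46.5% and 0% of 1.5-fold changes. With the fold limit of a call added, 40.5%, 48.5% and 39.5% of the 2-fold changes were recovered. The simulation gave every gene of a class the same spread, also in the monoculture, so these shares need not hold for the real counts.

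RNA from broken cells reaches every droplet. Its share per class and co-culture library was estimated from genes under 2 CPM in the monoculture and at least 100 CPM in the whole library, and ranged from 3.51% to 5.85% of UMIs. This expected free RNA was subtracted from the co-culture sums, not from the monocultures, before a second fit as an alternative. Negative results were set to 0. A gene whose co-culture counts were emptied this way then shows a large negative change, which is no measured fall in the cells. Comparisons with 1 library per side (the lines with each other, day 8 with day 0) are log2 ratios of CPM with a prior of 1 CPM over genes with at least 10 CPM in one of the sums, without a test. Their exact Poisson intervals, and the exact Clopper-Pearson 95% intervals of shares, cover counting error only. A fold against 0 counts is a lower bound set at 3 counts per sum. Similarity was Spearman's correlation across genes of log2(CPM + 1), and genes are not independent replicates.

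Genes are named by a rule. From each co-culture comparison it takes called genes with both replicates on the same side of the monoculture and at least 20 CPM, namely the 8 with the largest change each way that were not partner-enriched and the 4 largest partner-enriched ones. From each of 31 gene lists it takes up to 4 called members, or the 2 most highly expressed where none was called. From each comparison of single libraries it takes the 6 largest ratios each way among genes with at least 50 CPM, and up to 4 members per list. The comparisons, gene lists, cell markers, tests, naming rule and most alternatives were set before the data were examined. The clustering settings, the reading of the clusters, each cluster on its own, and whole libraries in place of classes were chosen after seeing the data. The alternatives set beforehand were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, sums thinned to equal depth, doublets kept, assignment by multinomial likelihood, a stricter cell filter (2000 genes, 10% mitochondrial), subtraction of free RNA, all 9 sums in 1 fit, other priors (0.1 and 10 CPM), TMM-scaled CPM, at least 50 CPM or Pearson's r for similarity, and leaving out each co-culture replicate. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 did the remaining work.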

Results

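Single-cell transcriptomes were compared among mouse blastocysts, their outgrowths in culture, and stem cell lines that stand for the 3 lineages of the blastocyst: the epiblast (ESC), the trophectoderm (TSC) and the primitive endoderm (XEN). The title names cross-talk between embryonic and extra-embryonic cells as the subject, and the design sets each line alone against the same line grown with the other two for 5 days. Total UMIs per library were 25260127 in the blastocyst, 68028451 in the outgrowth, 51206717 in the ESC, 64064558 in the TSC and 57800536 in the XEN monoculture, and 101117080 and 103431608 in co-culture replicates 1 and 2. After filtering, the blastocyst kept 129 of 380 barcodes, with a median of 184344 UMIs, and the median mitochondrial share of all its barcodes was 72.8%. The outgrowth kept 5588 of 6853 barcodes, the ESC, TSC and XEN monocultures 9502, 8560 and 8989, and the co-cultures 10676 and 10053. Their median UMIs per kept cell were 10180.5 in the outgrowth, 4528, 5825 and 5521 in the monocultures, and 8116.5 and 8399 in the co-cultures. Co-cultured cells were thus sequenced more deeply than the monocultures they were compared with. Nothing in the labels says that the 2 co-culture replicates came from separate cultures, so p-values measure only the spread between these samples, and the lone monoculture of each line was assumed to vary like the co-culture pair. The spread was pooled over genes by a prior whose median degrees of freedom were 145 in ESC-like, infinite in TSC-like and 7.31 in XEN-like cells. Small p-values in ESC-like and TSC-like cells thus rest almost wholly on the pooled spread. Numbers of genes past the test are not comparable between the classes. The replicates differed by more than sampling noise, with a chi-square per degree of freedom of 6.74 in ESC-like, 12.05 in TSC-like and 23.0 in XEN-like cells. That shows only that they are not copies of 1 library, and they were counted as 2 samples because the labels list them so. Values from single libraries have no replicate check.

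The first comparison asked what each line contributed after co-culture. XEN-like cells, marked by primitive endoderm genes such as Dab2, Cubn and Spink1, made up most of the co-culture, with 53.6% ± 1.11 (SD, n = 2 libraries). TSC-like cells, led by Krt7, Hand1 and Elf5, made up 21.3% ± 3.14, and ESC-like cells, led by Fgf4, Dppa5a and Tdgf1, 14.3% ± 2.40. In replicate 1, of 9562 cells without doublets, 52.8% (51.8 to 53.8) were XEN-like, 23.5% (22.7 to 24.4) TSC-like and 12.6% (11.98 to 13.3) ESC-like. In replicate 2, of 9063 cells, the shares were 54.4% (53.4 to 55.4), 19.1% (18.3 to 19.9) and 16.0% (15.3 to 16.8). The plating ratio is not in the labels, so gains or losses were not computed. In the monocultures the line's own class held 89.3% (ESC), 79.6% (TSC) and 97.4% (XEN) of cells. Within the ESC line, clusters 2 and 6 held 60.9% and 31.1% of the monoculture, 35.0% and 53.5% of replicate 1, and 45.1% and 48.7% of replicate 2, so that cluster 2, led by Stra8, Lefty1 and Klf2, was the larger alone and cluster 6, led by Tcf15 and Tdgf1, the larger in co-culture. Cluster 11, led by the primitive streak genes T and Fgf8 and kept apart from the ESC-like class, held 8.07% of the ESC line alone and 11.5% and 6.25% of it in replicates 1 and 2. In the TSC line, cluster 1 was the largest in all 3 libraries, at 55.9%, 53.9% and 54.4%. Cluster 9, led by the syncytiotrophoblast regulator Gcm1 and the CDK inhibitor Cdkn1c and also kept apart, held 12.7% of the TSC line alone and 13.2% and 14.9% in the replicates. In the XEN line, cluster 3 led alone with 34.3%, cluster 4 led in replicate 1 with 38.8%, cluster 3 led in replicate 2 with 36.0%, and cluster 8 held 23.2% alone against 11.8% and 7.71%. Fibroblast-like cells, which express Dcn and Col1a2 as feeder fibroblasts do, held 2.80% and 1.92% of the co-cultures, and a cluster led by the macrophage genes Lyz2, Pf4 and C1qa held 2.47% and 1.69%. In the ESC, TSC and XEN monocultures the former held 1.11%, 5.09% and 0.834% and the latter 0.680%, 3.75% and 1.45%, so both were scarcer in co-culture than in the TSC monoculture and more frequent than in the ESC monoculture. These shares compare cells of unlike depth, since the median UMI count was 4396.5 in monocultured against 8056 and 8040 in co-cultured ESC-like cells, 5446 against 7527.5 and 8405 in TSC-like cells, and 5330 against 7903 and 7979 in XEN-like cells.

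**Figure D1:**
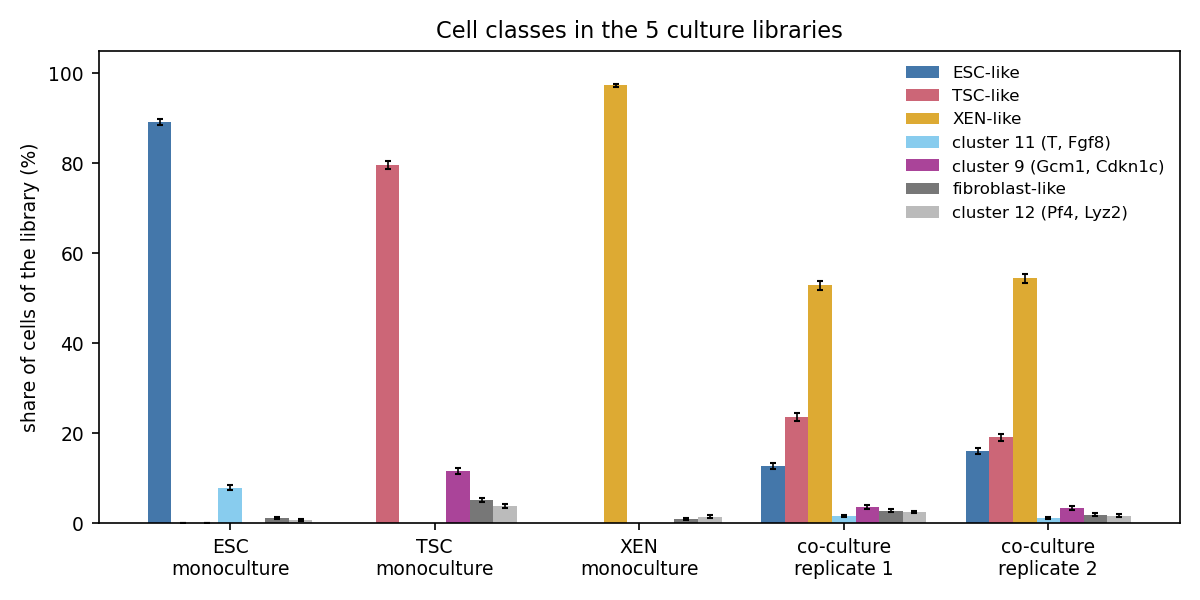
Percent of cells (vertical axis) per class in each culture library, with exact 95% binomial intervals as error bars. XEN-like cells held 52.8% and 54.4% of the co-cultures, TSC-like cells 23.5% and 19.1%, and ESC-like cells 12.6% and 16.0%.

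The next comparison asked how ESC-like cells changed when grown with TSC and XEN cells. Of naive and core pluripotency genes, 1 of 14 and 0 of 12 passed the test, while the immediate-early gene Fos rose 1.42 ± 0.12 on the log2 scale (SE, n = 2 co-culture libraries against 1 monoculture) and genes abundant in the partner lines rose with it. Of 12969 genes tested, 171 were called, 122 higher and 49 lower in co-culture, and 112 of the 122 were partner-enriched. Once the expected free RNA of the partner lines was subtracted, 59 genes were called, 16 higher and 43 lower. Fos (ENSMUSG00000021250, mm10 chromosome 12, 85473890 to 85477273), a transcription factor gene induced by growth factors and stress, went from 40.6 CPM to 129 and 93.6 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.4e-19). The related gene Fosb rose from 8.48 to 46.8 and 34.9 CPM, and Jun rose 1.03. Among genes with at least 20 CPM, the largest falls were those of Hist1h2ap (ENSMUSG00000094777, mm10 chromosome 13, 21833026 to 21833507; log2 change -2.53 ± 0.14, adjusted p = 7.5e-36), which encodes a replication-dependent histone, Uba52 (-1.91), a ubiquitin-ribosomal fusion gene, and Gstp1 (-1.69), a glutathione transferase. These 3 have near-identical paralogs or pseudogenes and their assignment is uncertain, as is that of the histone gene Hist1h2ae (-1.09). Stra8 (-1.44), a retinoic acid responsive gene, and Phb (-1.02), a mitochondrial chaperone gene, also fell. Stra8 leads cluster 2, whose share of the ESC line was lower in co-culture, so a changed cluster mix could contribute to its fall. No named call that could be tested within cluster 2 or 6 turned sign there. Of partner-enriched genes with at least 20 CPM, the largest gains were those of Clu (3.64 ± 0.18, from 2.26 CPM to 25.9 and 31.5), Fosb (2.23), the laminin gene Lamb1 (2.08) and the keratin gene Krt8 (1.93); after subtraction of free RNA Lamb1 and Krt8 stood at -0.29 and -2.24, Clu at 1.94 and Fosb at 2.23. Igf2, a partner-enriched growth factor gene abundant in TSC (687 CPM), went from 0.133 CPM to 18.1 and 14.6 CPM in ESC-like cells and stayed called after subtraction, with a log2 change of 5.36. XEN-like cells of the same libraries reached similar levels, so free RNA above the estimated share is not excluded for this gene.

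By fixed gene groups, 1 of 14 naive pluripotency genes rose in ESC-like cells (Nr0b1, 0.46) and 13 did not pass, among them Tdh (-0.06) and Klf2 (0.10). None of 12 core pluripotency genes passed, with Dppa5a at -0.16 and Tdgf1 at -0.06. For these counts of 0 called genes, edgeR at unadjusted p under 0.05 gave 2308 genes in the class as a whole and DESeq2 called 41. Of 15 formative and primed genes, 3 rose (Cdh2 1.32, Foxd3 0.86, Zic3 0.40) and Zic2 fell (-0.62); adjusted over the list alone, 5 rose and 1 fell. Of 6 primitive streak genes, Cdx1 fell (-0.75) and Foxa2, also an endoderm gene, rose. In all 5 were lower, the median was -0.34 (percentile 0.920), and 3 fell when adjusted over the list alone. Cluster 11, led by T and Fgf8, is not part of this class. None of 5 neural genes passed, with Tubb3 at -0.12 and Nes at -0.22. Targets of FGF/ERK signalling had a median change of 0.28, in percentile 100 of random lists, and 3 of 11 rose (Dusp4 0.74, Spry2 0.72, Dusp6 0.49), or 6 when adjusted over the list alone. Among 11 TGF-beta/Nodal targets, Lefty1 (-0.81) and Lefty2 (-0.41), secreted Nodal antagonists, fell, and the partner-enriched Serpine1 (1.79) and Ccn1 (1.18) rose. Lefty1, like Stra8, leads cluster 2, so the changed cluster mix could contribute to its fall too. Of 7 BMP targets, Id3 fell (-0.68) and Id2 rose (0.93), but after subtraction of free RNA 0 of 6 tested rose and 1 fell. Cdx1 was the 1 of 10 WNT targets to fall and none rose. Primitive endoderm genes, which ESC lack, rose in 10 of 10 cases (Gata4 4.04, Dab2 3.37, Sox17 3.14), all of them partner-enriched; after subtraction only 2 of them could be tested, and neither passed. Likewise 6 of 9 parietal endoderm genes rose (Plat 2.97, Srgn 2.75), 7 of 13 basement membrane genes (Lama1 3.34, Col4a2 2.57, Col4a1 2.38), and 4 of 14 trophoblast stem genes (Hand1 3.39), each of these partner-enriched, while the trophoblast gene Tfap2c fell (-0.78). After subtraction of free RNA Srgn stood at -7.37, Lama1 at -0.24, Col4a2 at -2.68 and Col4a1 at -9.16, and no parietal endoderm or basement membrane gene rose while 2 and 3 fell. Values such as -7.37 and -9.16 come from co-culture counts emptied by the one-sided subtraction, so they are not measured falls in the cells. None of 4 visceral endoderm genes passed, with Apoe at 0.02. Cdkn1c rose (0.68) among 3 differentiated trophoblast genes, but none of the 3 rose after subtraction of free RNA.

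Of 25 G1/S genes Ccnd3 (-0.40) and Ung (-0.49) fell, and none of 22 G2/M genes passed, with Top2a at 0.05. Of 15 p53 targets and CDK inhibitors, 3 rose (Perp 0.83, Btg2 0.61, Trp53inp1 0.54), and the median was 0.23 (percentile 99.99 of random lists). None of 16 hypoxia and glycolysis genes (Aldoa -0.22), 12 integrated stress response genes (Asns 0.04) or 15 MYC targets (Npm1 0.10) passed, though the median of the integrated stress response genes was 0.20 (percentile 99.81), and 1 of 14 cholesterol synthesis genes fell (Mvd -0.36). Among 11 dissociation and heat shock genes, Fosb, Fos, Jun and Junb (0.42) rose and Ier2 fell (-0.41). Of 12 matrix receptors Itgb1 rose (0.37), and of 11 secreted ligands Igf2, Wnt7b and Wnt11 rose, all 3 ligands partner-enriched. After subtraction of free RNA no matrix receptor rose, and 1 ligand did. Of 10 interferon genes the partner-enriched B2m rose (1.30) and Oasl2 fell (-0.95). After subtraction of free RNA 1 of the 10 rose, by less than 2-fold, and 1 fell. Zscan4d, which marks the 2-cell-like state, fell from 0.824 CPM to 0 and 0.0800 CPM (adjusted p = 0.0049), 1 of 2 genes of that list tested. Of 16 imprinted genes 7 rose, among them H19 (1.13), Grb10 (1.07), Rian (0.71) and Meg3 (0.50). The 3 called were H19, Grb10 and Igf2, all partner-enriched. After subtraction of free RNA 5 of the 16 rose and only Igf2 was still called. Xist rose (2.12) among 2 sex chromosome genes, Col1a2 (1.85) and Dcn (1.74) among 7 fibroblast genes, and Lyz2 (1.25) among 2 blood and endothelial genes, all partner-enriched; after subtraction of free RNA Xist stood at -7.73, and Col1a2 (1.27), Dcn (0.44) and Lyz2 (0.15) did not pass. These fibroblast and macrophage genes moved the same way as the shares of those cells. Assignment by likelihood, which also placed cells of the clusters kept apart, left 104 calls, and DESeq2 left 41. Fitted with cluster 2 or 6 alone, which differ in share between the libraries, 150 and 117 genes were called.

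**Figure D2:**
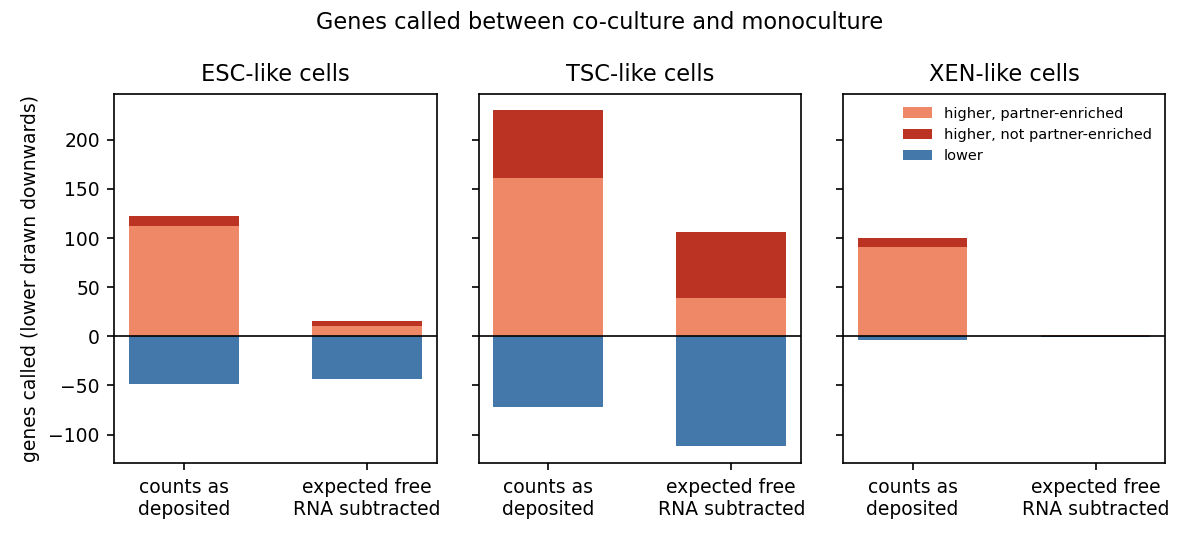
Genes called between co-culture and monoculture (vertical axis, number of genes) in each class, higher and lower in co-culture, split into partner-enriched genes and the rest, before and after subtraction of free RNA. Of 122, 230 and 100 genes called higher in ESC-like, TSC-like and XEN-like cells, 112, 161 and 91 were partner-enriched.

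For TSC-like cells the same question was asked. The order of the classes by number of calls turned with the method, from 302 in TSC-like, 171 in ESC-like and 104 in XEN-like cells to 40, 41 and 80 by DESeq2, 285, 175 and 320 with doublets kept, and 256, 121 and 270 with all 9 sums in 1 fit. Hypoxia and glycolysis genes rose together, with 14 of 16 past the test and a median log2 change of 0.62 (percentile 100 of random lists), while 3 of 6 differentiated trophoblast genes, 4 of 11 WNT, 4 of 9 BMP and 6 of 15 MYC targets fell. Of 13558 genes tested, 302 were called, 230 higher and 72 lower, and 161 of the 230 were partner-enriched; at any size, 1075 genes rose and 1128 fell. After subtraction of free RNA 218 were called, 106 higher and 112 lower. Ndrg1 (ENSMUSG00000005125, mm10 chromosome 15, 66929318 to 66969640), a hypoxia-induced gene, rose 1.13 ± 0.13 (SE, n = 2 against 1), from 79.3 to 152 and 182 CPM (edgeR quasi-likelihood, adjusted p = 8.5e-15). Ero1l, an oxidase of the endoplasmic reticulum, rose 1.13, and the partner-enriched vasodilator gene Adm rose from 1.25 to 2.80 and 3.92 CPM. Milder rises included Bnip3 (0.66), Pgk1 (0.58), Slc2a1 (0.56), the main glucose transporter gene, and Hk2 (0.43). Outside that list the glycolytic genes Eno2 (1.43 ± 0.15) and Pfkfb3 (1.38 ± 0.13) rose, as did Tfpi (1.61 ± 0.14, from 89.1 to 202 and 319 CPM), an inhibitor of coagulation, Fos (1.15), Tuft1 (1.09) and the non-coding RNA Snhg6 (1.06). Among falling genes, Dkk1 (ENSMUSG00000024868, mm10 chromosome 19, 30545863 to 30549665), a secreted WNT antagonist, went from 35.1 to 14.7 and 9.91 CPM (-1.45 ± 0.13, adjusted p = 4.0e-26). Mat2a, which makes S-adenosylmethionine, changed by -1.39, the interferon-induced Isg15 by -1.29, Sox3 by -1.11, Ints5 by -1.06, and Gpatch4 by -1.03. At that level of expression, the largest partner-enriched gains were those of Dppa5a (2.59), Apoe (1.66), Lpin1 (1.501) and Vim (1.34). After subtraction Lpin1 stood at 1.480, Dppa5a at -0.20, Apoe at -0.58 and Vim at -11.39. The value of Vim comes from co-culture counts emptied by the one-sided subtraction and is no measured fall.

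**Figure D3:**
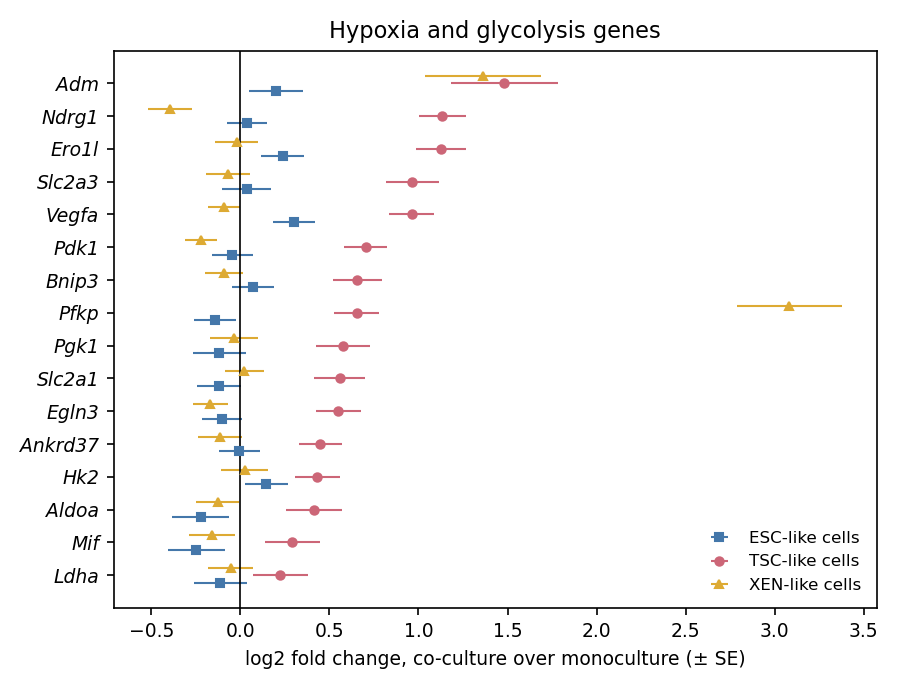
Log2 fold change of the hypoxia and glycolysis genes (co-culture against monoculture, with SE) in each class. In TSC-like cells 14 of 16 rose and the median was 0.62, against -0.03 in ESC-like and -0.08 in XEN-like cells.

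Among trophoblast groups, 3 of 6 differentiated trophoblast genes fell by at least 2-fold in TSC-like cells, namely Plac1 (-1.82, from 13.6 to 3.88 and 3.44 CPM), a placental growth gene, Gcm1 (-1.12) and Phlda2 (-1.04), an imprinted restrainer of placental growth, while Slc2a3 rose (0.96). The class leaves out cluster 9, led by Gcm1, which held 12.7% of the TSC line alone and 13.2% and 14.9% in co-culture. These falls therefore do not show less differentiation in the line as a whole. Of 16 trophoblast stem genes 5 fell by less than 2-fold (Eomes -0.59, Cdx2 -0.56, Ascl2 -0.52, Id2 -0.42, Elf5 -0.38) and Gata3 rose (0.49). Of 11 WNT targets Lgr5 (-2.82), Notum (-1.35), Axin2 (-0.81) and Cdx2 fell and the cyclin gene Ccnd1 rose (0.78). Of 9 BMP targets, 4 fell (Smad6 -0.78, Id1 -0.74, Msx2 -0.60 and Id2) and Msx1 rose (0.56). FGF/ERK targets rose in 3 of 12 cases (Ier3 0.97, Dusp4 0.75, Etv5 0.41), or 6 when adjusted over the list alone. Of 10 TGF-beta/Nodal targets, 4 rose, among them Ccn2 (0.96) and Ccn1 (0.71), and Nodal fell (-0.94). Among 15 secreted ligands Vegfa, an angiogenic factor, rose (0.96), as did the partner-enriched Wnt11 (1.13; -1.08 after subtraction of free RNA and -0.29 in cluster 7 alone) and Fgf4, and Nodal and Dkk1 fell. Growth-related groups moved by less than 2-fold: 8 of 15 p53 targets and CDK inhibitors rose (Cdkn1a 0.63, Cdkn1b 0.59, Mdm2 0.56), with a median of 0.52, 6 of 15 MYC targets fell (Hspd1 -0.57, Ncl -0.45), with a median of -0.34, and 7 of 25 G1/S genes fell (Fen1 -0.75, Ccne1 -0.60), while 2 of 22 G2/M genes rose (Nusap1 0.46). Of 11 interferon genes, 5 fell (Ifit1 -1.65, Isg15 -1.29, Oasl2 -0.67) and the partner-enriched Ifitm1 rose. Of 12 integrated stress response genes 4 rose (Vldlr 0.99, Ddit3 0.95, Ddit4 0.75), and 1 of 14 cholesterol synthesis genes did (Msmo1 0.39). Dissociation and heat shock genes split, with Fos and Fosb (0.93) rising and Hspa1b (-0.76), Hspb1 (-0.56) and Hsph1 (-0.43) falling among 11. Of 13 matrix receptors 3 rose (Itgav 0.64, Sdc4 0.47, Itga3 0.38).

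Genes of the partner lineages also rose in TSC-like cells. This held for 10 of 11 primitive endoderm genes (Sox17 3.83, Gata4 1.68), the other one, Foxq1, falling (-0.80), for 7 of 10 parietal endoderm genes (Srgn 3.87, Plat 2.16), 9 of 13 basement membrane genes (Lama1 4.15, Lamc1 0.77, Fn1 0.51), 1 of 4 visceral endoderm genes (Apoe), 4 of 12 core pluripotency genes (Dppa5a, Tdgf1 at 0 UMIs alone and 5.70 and 6.31 CPM in co-culture) and 3 of 11 naive genes (Nanog 2.13, Klf4 0.78). After subtraction of free RNA 6 of the 11 primitive endoderm genes could be tested, of which none rose and 3 fell. Srgn then stood at -6.83 and Lama1 at -7.26, with 3 parietal endoderm genes rising and 3 falling, and 3 basement membrane genes rising and 1 falling. Of 10 core pluripotency genes tested 1 then rose and 1 fell, and of 9 naive genes 0 rose and 1 fell. In the counts as deposited L1td1 (-0.58) fell in the core group and Tbx3 (-0.91) in the naive group. Among 12 formative and primed genes Etv5 rose and Sox3 fell, among 6 primitive streak genes Foxa2 rose (1.11, but -0.44 after subtraction) and Eomes fell, and among 3 neural genes Tubb3 fell (-0.77). Of 16 imprinted genes Meg3 (0.51) and Rian (0.50) rose and Phlda2, Mest (-0.72) and Ascl2 fell. None of 5 sex chromosome genes passed the edgeR test (Xist 0.24, Tsix 0.27), beside 3872 genes at unadjusted p under 0.05 and 40 called by DESeq2 in the class. Of 10 fibroblast genes Col1a1 fell (-1.77) and Twist1 rose (0.67), and Lyz2 fell (-0.69) among 4 blood and endothelial genes, Col1a1 and Lyz2 moving as the shares of fibroblast-like and macrophage gene cells did. Genes of the 2-cell-like list were too low to test in TSC-like and XEN-like cells. DESeq2 called 40 genes in place of 302, and cluster 7 alone gave 193.

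In XEN-like cells Egr1 (ENSMUSG00000038418, mm10 chromosome 18, 34859823 to 34864984), an immediate-early transcription factor gene, fell from 76.6 to 6.87 and 6.19 CPM, a log2 change of -3.60 ± 0.11 (SE, n = 2 against 1; edgeR quasi-likelihood, adjusted p = 2.3e-06). Rspo3, which encodes a WNT agonist, rose 1.480 ± 0.15, from 8.71 to 22.7 and 27.5 CPM, and the antioxidant gene Prxl2a rose 1.14 ± 0.14. None of the 3 was called without the low-count filter or at equal depth: Egr1 kept its size and spread (-3.60 ± 0.09 and -3.60 ± 0.10), but its adjusted p was 0.714 and 0.152, as the fit's median prior degrees of freedom went from 7.31 to 1.72 and 2.23. Of 13585 genes tested 104 were called, 100 higher, 91 of them partner-enriched, and 4 lower. The 4 lower genes were Egr1, Atcayos (-2.02), Fam184b (-1.87) and Glra1 (-1.44), the last 3 named after their values were seen. After subtraction of free RNA 2 genes were called, Igf2 higher and Egr1 lower. Igf2 went from 0 UMIs alone to 17.9 and 15.2 CPM in co-culture, levels like those in ESC-like cells. Its gain was 1.83 times the expected free RNA, so a free RNA share that varies between genes could give it. With the same limit of 20 CPM, partner-enriched genes rose most in the case of Dppa5a (from 0.0657 to 36.5 and 34.9 CPM), Bex1 (4.09) and the calcium-binding gene S100a6 (1.30), which stood at -2.18 (Bex1) and -0.15 (S100a6) after subtraction.

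Of 11 primitive endoderm genes in XEN-like cells, Foxq1 rose (0.93) and Cubn (-0.76) and Lrp2 (-0.55), endocytic receptors of the yolk sac endoderm, fell, each by less than 2-fold. The median of the group was -0.25 (percentile 0 of random lists) and Gata4 stood at -0.06. Nid1 (-0.62) was the 1 of 13 basement membrane genes to fall, with Sparc at -0.27 and Col4a1 at -0.24, and among 9 parietal endoderm genes it fell while the partner-enriched Krt19 rose (3.13). None of 10 visceral endoderm genes passed (Apoe -0.18). Pluripotency and trophoblast genes, all or nearly all partner-enriched, rose in 5 of 12 naive (Klf2 2.87, Tdh 1.31), 7 of 12 core (Utf1, from 0 UMIs to 4.93 and 5.48 CPM), 1 of 12 formative and primed (Pou3f1 3.65), 4 of 14 trophoblast stem (Hand1, from 0 UMIs to 3.44 and 2.95 CPM; Elf5 3.102) and 2 of 4 differentiated trophoblast cases (Cdkn1c 4.29, Phlda2 2.82). In the naive group Tbx3 (0.76) was not partner-enriched. Imprinted genes rose in 8 of 15 cases (Meg3 2.59, Peg10 1.24), all 8 partner-enriched, and after subtraction of free RNA 1 of 12 tested rose. Of 12 FGF/ERK targets the partner-enriched Ier3 rose (2.01) and Egr1 fell, and after subtraction of free RNA none rose. Of 11 TGF-beta/Nodal targets 3 rose (Serpine1 4.18, Smad7 0.77), of 15 p53 targets and CDK inhibitors 2 (Perp 1.43), of 15 secreted ligands 2 (Igf2, Fgf4), of 16 hypoxia and glycolysis genes 1 (Pfkp 3.08), of 15 MYC targets 1 (Mycn 0.60), of 2 neural genes 1 (Tubb3 0.83) and of 3 sex chromosome genes 1 (Xist 3.91, but -7.02 after subtraction of free RNA). The called TGF-beta/Nodal, p53 and hypoxia genes were all partner-enriched. After subtraction no gene of these groups rose, in a fit that called 2 genes in the whole class. Among 10 dissociation and heat shock genes Hspb1 rose (0.87) and Ier2 fell (-0.72). None passed among 25 G1/S genes (Pcna 0.04), 22 G2/M genes (Top2a 0.04), 12 matrix receptors (Itgb1 0.01), 14 cholesterol synthesis genes (Fdft1 0.30), 12 integrated stress response genes (Atf4 -0.19), 11 interferon genes (Bst2 0.56), 6 WNT targets (Tcf7 0.30), 8 BMP targets (Id3 -0.04), 3 primitive streak genes (Foxa2 0.04), 10 fibroblast genes (Fbn1 0.69) or 5 blood and endothelial genes (Lyz2 0.90), beside 1298 genes at unadjusted p under 0.05 by edgeR and 80 called by DESeq2 in the class. Adjusted over the list alone, 8 of 14 trophoblast stem, 7 naive and 10 imprinted genes were called higher, while at any size 4 integrated stress response genes fell and 1 rose (median -0.24, percentile 0), 5 primitive endoderm genes fell and 1 rose, and 4 interferon genes rose. All 14 cholesterol synthesis genes were higher, with a median of 0.16 (percentile 100), and 1 rose over the list alone. The number of calls was the least stable of the 3 classes: edgeR called 0 genes without the low-count filter and 0 at equal depth, where 1193 and 1039 passed unadjusted p under 0.05, and 320 with doublets kept.

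A test of the difference asked which co-culture effects were unlike between classes. Effects differed for 152 genes between ESC-like and TSC-like, 295 between ESC-like and XEN-like, and 415 between TSC-like and XEN-like cells. Of these, 21, 8 and 30 had been tested in both classes alone and were partner-enriched in neither. Egr1 differed by 3.26 ± 0.15 (log2, SE; adjusted p = 3.6e-08, edgeR) between ESC-like and XEN-like cells and by 3.86 ± 0.15 (adjusted p = 8.9e-09) between TSC-like and XEN-like cells. The hypoxia gene Ndrg1 differed by 1.47 ± 0.19 (adjusted p = 4.5e-04) between TSC-like and XEN-like cells, Eno2 by 1.56, Ero1l by 1.10 and Mat2a by -1.55. In this fit of all 9 sums, with at least 2-fold required on both sides, Plac1 and Fam171b moved in opposite directions in ESC-like and TSC-like cells, and so did Phlda2 in TSC-like and XEN-like cells. In the class where it rose, each of the 3 was lower alone than in a partner line: Plac1 went from 0 UMIs to 2 and 6 UMIs in ESC-like cells, against 13.6 CPM in the TSC line, and after subtraction of free RNA neither Phlda2 in XEN-like cells (1.23) nor Fam171b in TSC-like cells (1.02) passed. With effects of any size on both sides at adjusted p under 0.05, 16, 17 and 37 genes did so in the 3 pairs, as Jun did in ESC-like and XEN-like cells, a count added after the values were seen. Fam171b was named after its values were seen. The 3 classes of a co-culture library share that library, so their effects are not independent. After subtraction of free RNA 63, 37 and 100 genes differed, and without the low-count filter 244 did between ESC-like and TSC-like cells.

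The lines alone were compared to show what separates them, with 1 library each. ESC expressed pluripotency genes, TSC trophoblast genes and XEN endoderm and matrix genes, in each case by large margins. Dppa5a (ENSMUSG00000060461, mm10 chromosome 9, 78367052 to 78368177), a pluripotency-associated gene, had 6535 CPM in ESC, 9.11 (8.22 to 10.1) in TSC and 0.0657 (0.0135 to 0.192) in XEN. Tdgf1, a Nodal co-receptor, had 719 CPM in ESC and 0 UMIs in TSC and XEN, at least 9990-fold and 10942-fold higher. TSC exceeded ESC in Hand1 (272 against 0.346 CPM), a trophoblast transcription factor gene, in Igf2 (687 against 0.133 CPM), Xist (605 against 1.33 CPM), Krt18 and Rhox6. XEN exceeded ESC in Dab2 (504 against 0.744 CPM), an endocytic adaptor gene, Lama1 (503 against 1.22 CPM), a basement membrane laminin, Col4a1, Cited1 and Ctsh. Among genes with at least 10 CPM, 2125 of 8213 differed over 2-fold between ESC and TSC (729 higher in ESC), 2490 of 8193 between ESC and XEN (986 higher in ESC) and 1951 of 8293 between TSC and XEN (1099 higher in TSC). Larger prior counts left fewer, 1230, 1626 and 1289 with 10 CPM.

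By group, 10 of 12 naive and 8 of 12 core pluripotency genes were over 2-fold higher in ESC than in TSC (Nanog 6.10, Dppa5a 9.34), and 9 of 12 in both groups than in XEN (Klf2 7.00, Tdh 6.88). Of 12 formative and primed genes 8 and 10 were higher (Zic3 3.82 against TSC), though Pou3f1 was higher in TSC (-3.52). Trophoblast stem genes were lower in ESC in 12 of 15 cases (Id2 -6.35) and higher in TSC than in XEN in 14 of 15 (Elf5 7.03). Primitive endoderm genes were higher in XEN in 11 of 11 cases against either line (Gata4 -7.52, Sox17 -6.56 in ESC against XEN), parietal endoderm genes in 7 of 8, and basement membrane genes in 11 of 13 against ESC and 9 of 13 against TSC. FGF/ERK targets were higher in ESC than XEN in 7 of 9 cases (Ier3 5.23, Etv5 3.01), WNT targets in 4 of 4 (Ccnd1 4.35), and Nodal targets in 5 of 9 (Lefty1 5.00). TSC exceeded ESC in 6 of 9 interferon genes (Isg15 -4.95), 7 of 14 p53 targets and CDK inhibitors (Perp -4.87), 5 of 9 matrix receptors (Itgb5 -3.11) and 9 of 15 imprinted genes (H19 -4.89, Grb10 -4.11), and imprinted genes were over 2-fold higher in TSC than XEN in 11 of 14 cases (Cdkn1c 8.14). Between TSC and XEN, secreted ligands were higher in TSC in 7 of 10 cases (Wnt7b 5.59) and BMP targets in 3 of 5 (Id2 4.79), and integrated stress response genes were lower in 5 of 11 (Chac1 -3.23). Cell cycle groups differed less, with 18 of 24 G1/S and 22 of 22 G2/M genes within 2-fold between ESC and TSC. Hypoxia and glycolysis genes were within 2-fold in 12 of 16, 8 of 16 and 11 of 15 cases, with TSC lowest (median -0.57 against XEN). TMM scaling subtracted -0.15 from every ratio of ESC against TSC and -0.05 from those of ESC against XEN, which raised both, and 0.11 from those of TSC against XEN, and turned the split between ESC and TSC to 871 higher and 1141 lower and that between TSC and XEN to 986 and 999, so which of TSC and XEN has more higher genes is not settled.

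Blastocysts and day 8 outgrowths were compared to follow epiblast-like and trophectoderm-like cells from embryo to culture, with 1 library per time and unlike dissociation. Epiblast-like cells numbered 38 at day 0 and 37 at day 8. Clusters 3 and 4 of the blastocyst, with 28 and 26 of its 129 cells, were not named. The day 0 cluster was led by Sox17, a primitive endoderm gene, with the epiblast gene Tdgf1 also among its 10 leading genes, and only 3 of 14 epiblast markers were enriched in it, so its name is uncertain and the values below compare 2 clusters that are not surely of 1 cell type. Dppa3, a maternal factor gene, had 3306 CPM at day 0 and 83.9 CPM at day 8, while Bex1 had 1.19 (0.479 to 2.45) and 1190 CPM and the membrane protein gene Ifitm3 0.681 (0.185 to 1.74) and 666 CPM. Mgarp had 432 CPM at day 0 and 0 UMIs at day 8, at least 77.3-fold lower, and Fbp2, Crxos, Olfr1459, Bhmt and Timd2 were also far lower. Stmn2, Igfbp2, Ldhb and Ifitm1 were far higher. Of 11 formative and primed genes 7 were over 2-fold higher at day 8 (Sox11 3.99, Pou3f1 3.58) and none lower, and so were 5 of 7 TGF-beta/Nodal targets (Smad7 3.36), 6 of 6 secreted ligands (Bmp4 4.56), 7 of 11 FGF/ERK targets (Spry4 2.98), 6 of 7 interferon genes, 9 of 13 hypoxia and glycolysis genes (Pdk1 4.35) and 8 of 13 imprinted genes (Phlda2 5.01). Naive genes split, 4 higher (Tdh 2.92) and 3 lower (Fbxo15 -3.18) among 14, and Pou5f1 was lower (-4.16). The 4 primitive endoderm genes measured were all lower (Gata6 with 430 CPM at day 0 and 1.87, 0.0472 to 10.4, at day 8). In trophectoderm-like cells (37 and 1793 cells) H19 (ENSMUSG00000000031, mm10 chromosome 7, 142575529 to 142578143), an imprinted non-coding RNA, went from 0 UMIs to 2003 CPM, at least 4858-fold, and Ldha, the lactate dehydrogenase gene, from 1.65 (0.852 to 2.88) to 1009 CPM. Morc4, Rhox6, Bex1 and Rhox9 were also far higher at day 8. Dppa3 (2882 to 1.45 CPM), Calcoco2 (3809 to 6.39 CPM), Pou5f1, Bhmt, Alppl2 and Khdc3 were lower. Of 16 trophoblast stem genes 8 were higher (Hand1 6.70, Elf5 5.65) and 4 lower, among them Cdx2 (-2.67). The 4 primitive endoderm genes measured were all lower here too (median -6.08). In the day 0 trophectoderm-like cluster 9 of 11 trophectoderm markers detected were enriched, but Lrp2 was among its 10 leading genes. A difference in cell type between the 2 times is therefore not excluded here either. Differentiated trophoblast genes were higher in 3 of 4 cases (Cdkn1c 5.24), imprinted genes in 11 of 15, hypoxia and glycolysis genes in 9 of 14 (Pfkp 4.77), basement membrane genes in 6 of 10 (Hspg2 3.73) and dissociation genes in 4 of 9 (Junb 3.99), and naive genes were lower in 7 of 10. Over 2-fold, 2991 of 8024 genes differed in epiblast-like cells (1718 higher at day 8) and 2609 of 8060 in trophectoderm-like cells (1272 higher). TMM scaling subtracted 0.34 from all epiblast-like ratios and turned that split to 1227 higher and 1846 lower, and turned that of trophectoderm-like cells from 1272 and 1337 to 1406 and 1246, so directions of small changes are not settled in either; the day 8 epiblast sum held 536176 UMIs against 5878033 at day 0.

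The last comparison asked which embryo cells each line resembles. Over genes with at least 10 CPM in a class sum, the ESC line was nearest to epiblast-like cells of the outgrowth (Spearman's rho 0.930 across genes), above the blastocyst cluster named epiblast-like (0.808). The TSC line was nearest to trophectoderm-like cells of the outgrowth (0.958, against 0.778 in the blastocyst). For ESC, 1 outgrowth class of another lineage, the trophectoderm-like cells, also lay above that blastocyst cluster (0.848), and the others lay below it (0.588 to 0.795). For TSC, the epiblast-like (0.821) and both primitive endoderm clusters (0.834 and 0.855) of the outgrowth lay above the matching blastocyst class, and the fibroblast-like cells (0.705) and the macrophage gene cluster (0.708) below it. The XEN line was nearest to an outgrowth primitive endoderm cluster led by Fst, Myl3 and Fxyd3 (0.921), above the one led by Cubn and Amn (0.869). In co-culture the values for the same pairs were 0.931 and 0.926 (ESC), 0.952 and 0.946 (TSC), and 0.925 and 0.924 (XEN).

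**Figure D4:**
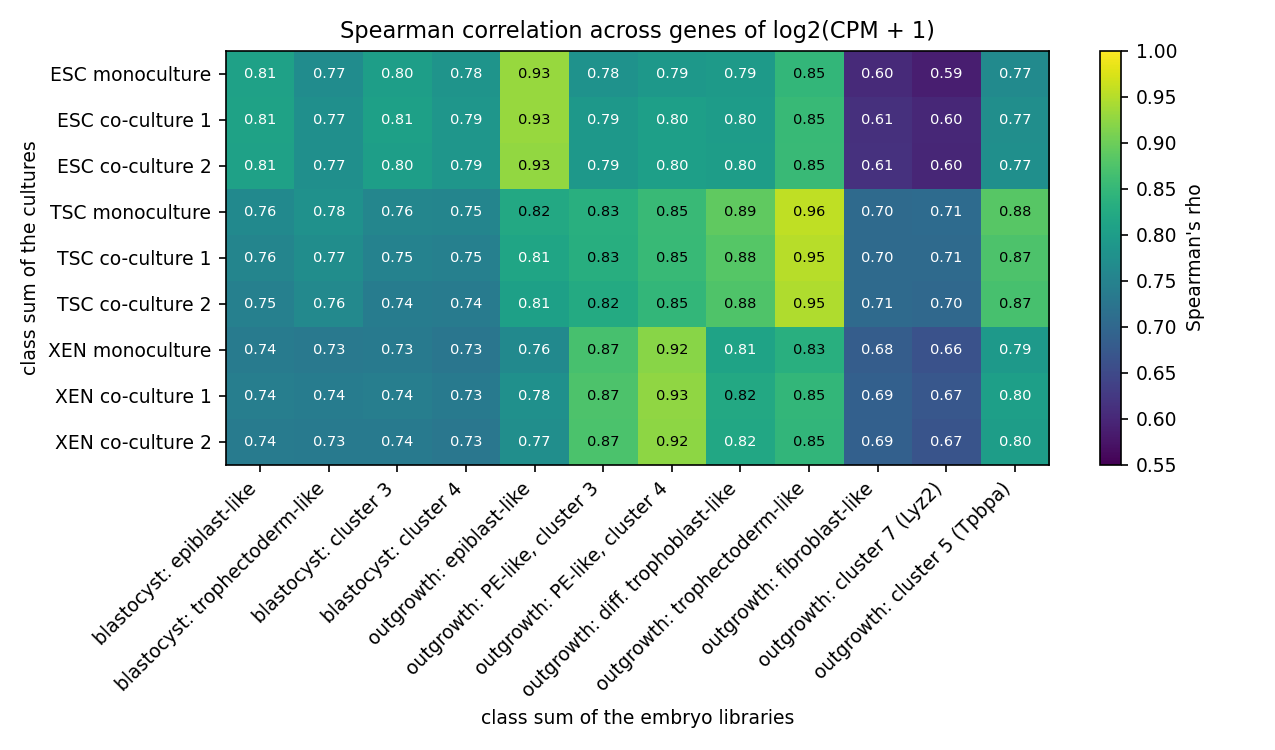
Spearman's rho across genes of log2(CPM + 1) between each line (rows, alone and in both co-culture replicates) and each class of blastocyst and outgrowth (columns), colour giving rho. The highest values were 0.930 for ESC, 0.958 for TSC and 0.921 for XEN alone, all with outgrowth classes.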

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

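Differences of the co-culture effect between classes were looked for throughout, and the values were 152 genes between ESC-like and TSC-like, 295 between ESC-like and XEN-like and 415 between TSC-like and XEN-like cells. Most of the named genes among them, 34, 44 and 47, were partner-enriched or untested in 1 of the classes. The other named genes were Ier3 (-1.16) and Mat2a (1.30) for ESC-like minus TSC-like cells, Egr1 (3.26), Gstp1 (-1.66) and Tubb3 (-1.04) for ESC-like minus XEN-like cells, and Eno2 (1.56), Ero1l (1.10), Ints5 (-1.07), Mat2a (-1.55), Ndrg1 (1.47) and Tfpi (1.46) for TSC-like minus XEN-like cells. Cell groups left out of the 3 classes included 87 cells of cluster 14 in the ESC monoculture and 173 cells of cluster 13 in co-culture replicate 2.

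For the rise of partner-line genes, the tests of free RNA as a whole and of doublets were set before the result was seen, and those of the part still called after subtraction were chosen after it. Free RNA from broken partner cells may account for most of this rise in ESC-like and XEN-like cells, where the median ratio of gain to expected free RNA was 1.09 and 1.18 and 79 of 98 and 66 of 72 genes were within 2-fold of it; in TSC-like cells the median was 1.61, but 83 of 153 were within 2-fold, 70 gained more, and the upper quartile was 9.36. Of partner-enriched genes still called higher after subtraction, 6 of 10 in ESC-like, 36 of 39 in TSC-like and 0 of 1 in XEN-like cells gained over 2-fold more than expected, which decides nothing because these genes were picked for gaining more. Remaining doublets could also bring in partner RNA. The 5% of cells richest in it held at most 21.9% of it, from 1.09 to 1.44 times what their depth predicts. A small group of doublets thus did not carry most of it. The UMIs were pooled over all these genes, so doublets stay open for the genes that gained more than expected. Partner contact that switches on these genes in the cells was not tested and remains open.

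For the hypoxia and glycolysis genes of TSC-like cells, the test of the cluster mix was set before the result was seen, and those of free RNA and of whole libraries were chosen after it. Free RNA could raise them, but after its subtraction the median was 0.64. Another mix of the 2 TSC-like clusters could do so too, yet the lower of the medians within clusters 1 and 7 was 0.57. A property of the whole co-culture libraries, such as depth or dissociation, would be likely to reach the other classes, where the higher median was -0.026. Those classes started from higher levels, with list medians of 0.49 for ESC against TSC and -0.57 for TSC against XEN in the monocultures. The lack of a rise there therefore does not exclude such a property. An effect of co-culture on TSC-like cells, for instance through oxygen use in a denser culture, and an unusual state of the lone TSC monoculture both stay open, and these data cannot separate them.

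For the immediate-early genes, the test of the XEN-like cluster mix was set before the result was seen, and those of handling were chosen after it. Handling of the co-culture libraries could shift these genes. The effects of 2 classes differed by 3.86 for Egr1 (TSC-like minus XEN-like), 1.56 for Jun (ESC-like minus XEN-like) and -1.16 for Ier3 (ESC-like minus TSC-like). After subtraction of free RNA the differences were 4.10, 1.39 and -1.23. A shift of equal size in all classes therefore does not account for these 3. Shared handling to which the cell types respond unequally is not excluded by this test. For Fos the largest difference was -0.29 and did not pass, nor did any for Fosb, Junb or Ier2, so for these 4 a shift of equal size is left open too. Another mix of XEN-like clusters was set aside for Egr1, whose smallest fall within a cluster was -3.37. Handling of a lone monoculture library, each class having its own, was not tested and stays open for all 7 genes, as does an effect of co-culture.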

How the results depend on the processing

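No paired analysis was possible because each monoculture exists once. The number of genes called in ESC-like cells was 171, against 41 by DESeq2, 104 with assignment by likelihood and 59 after subtraction of free RNA. In TSC-like cells it was 302, against 40 by DESeq2 and 193 in cluster 7 alone. In XEN-like cells it was 104, against 0 without the low-count filter, 0 at equal depth, 320 with doublets kept, 7 by likelihood, 2 after subtraction of free RNA, 270 with all 9 sums in 1 fit and 45 in cluster 8 alone. Subtraction of free RNA turned the share of calls that were higher from 71.3% to 27.1% in ESC-like, from 76.2% to 48.6% in TSC-like and from 96.2% to 50.0% in XEN-like cells. It lowered co-culture counts only. Partner-enriched genes called lower went from 2 to 19 in ESC-like and from 9 to 23 in TSC-like cells, and stayed at 0 in XEN-like cells. Genes whose effect differed between ESC-like and TSC-like cells numbered 244 without the low-count filter and 63 after subtraction, between ESC-like and XEN-like cells 37 after subtraction, and between TSC-like and XEN-like cells 100 after subtraction. The mean TSC-like share was 26.0% by likelihood, and the XEN-like share 52.0481% with doublets kept and 57.7% with the stricter cell filter. Assignment by likelihood kept at least 99.7% of the cells of each class in the co-cultures. It also placed the cells of clusters kept apart, so its sums differ mainly by the cells it added. With either replicate left out, the shares ranged from 12.6% to 16.0% (ESC), 19.1% to 23.5% (TSC) and 52.8% to 54.4% (XEN). No named call turned sign. For genes named by size the naming rule fixed this beforehand, since it required both replicates on the same side of the monoculture. Most partner-enriched calls moved in size (25 of 30 in ESC-like cells without replicate 1, 21 of 21 in TSC-like cells without replicate 2 and 26 of 27 in XEN-like cells with either left out), as did 11 of 21 other called genes of TSC-like cells without replicate 2. With a prior of 10 CPM, genes over 2-fold numbered 1230 (ESC and TSC), 1626 (ESC and XEN), 1289 (TSC and XEN), 1823 (epiblast-like) and 1683 (trophectoderm-like). TMM scaling turned the higher and lower counts from 729 and 1396 to 871 and 1141 for ESC and TSC, from 1099 and 852 to 986 and 999 for TSC and XEN, from 1718 and 1273 to 1227 and 1846 in epiblast-like cells, and from 1272 and 1337 to 1406 and 1246 in trophectoderm-like cells. Similarity to the nearest class was 0.934 (ESC), 0.943 (TSC) and 0.893 (XEN) with at least 50 CPM, and 0.935 (ESC) and 0.924 (XEN) by Pearson's r. Subtraction of free RNA turned the sign of Lamb1 (-0.29), Krt8 (-2.24), Srgn (-7.37), Fst (-1.10), Lama1 (-0.24), Col4a2 (-2.68), Col4a1 (-9.16) and Xist (-7.73) in ESC-like cells, of Dppa5a (-0.20), Apoe (-0.58), Vim (-11.39), Foxa2 (-0.44), Srgn (-6.83), Lama1 (-7.26) and Wnt11 (-1.08) in TSC-like cells, and of Bex1 (-2.18), S100a6 (-0.15) and Xist (-7.02) in XEN-like cells. Wnt11 was at -0.29 in cluster 7 alone, and Vim, 2.72 for ESC against TSC, was at -0.22 over all cells of the libraries. Turns after subtraction can follow from its one-sided form, since co-culture counts alone were lowered. The cause of the others was not tested.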

Other observations

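Igf2 and H19, imprinted neighbours of which Igf2 encodes a growth factor, stood in opposite order in trophectoderm-like cells of the outgrowth (134 CPM of Igf2, 2003 CPM of H19) and in the TSC line (687 and 71.3 CPM). Igf2 of TSC-like cells had 675 and 665 CPM in co-culture. Cdkn1c, which stops the cell cycle, had 318 CPM in the TSC line, 1930 CPM in its cluster 9 and 2619 CPM in an outgrowth trophoblast cluster led by the giant cell genes Prl7a1 and Prl3d1. The primitive endoderm of the outgrowth formed 2 clusters, with 16.8% and 11.4% of cells, the first led by Cubn and Amn and the second by Fst and Myl3. Epiblast-like cells of the outgrowth numbered 37 of 5282 (95% interval 0.494% to 0.964%).

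The 87 cells of cluster 14, 1.00% of the ESC monoculture, carried endoderm genes: 18 of 18 primitive endoderm markers measured were over 2-fold higher than in ESC-like cells (median 7.15), and 8 of 15 epiblast markers were lower. They were nearest to the Cubn and Amn cluster of the outgrowth (0.915), above the XEN line (0.877) and the ESC-like cells (0.853). The TSC and XEN monocultures held 0 such cells, and the co-cultures 6 and 10. With doublets kept the co-cultures held 144 and 206, more than the ESC monoculture on either count, but 138 and 196 of these were called doublets. Median UMI counts of the cluster there were 14856.5 and 16049.5, against 8116.5 and 8399 in the whole libraries. The larger count therefore does not show more endoderm-like cells in co-culture. The 173 cells of cluster 13, 1.91% of co-culture replicate 2 against 2 cells in replicate 1, were nearest to the TSC line (0.954). With doublets kept cluster 13 held 311 and 571 cells in replicates 1 and 2, of which 309 and 398 were called doublets.

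The test of the Y-linked genes was set before its result was seen. Y-linked UMIs were found in 229 of 6288 TSC-like cells of the monoculture (3.64%), at median depths of 6382 UMIs in these cells and 5446 UMIs in the class. Xist, which silences the X chromosome in female cells, was found in 27.5% of them (21.8 to 33.8) against 86.0% expected from other cells of like depth, a ratio of 0.32. The TSC line may therefore hold a minor part of cells with a Y chromosome. The ESC and XEN lines had 1.33 and 0.372 CPM of Xist and Y-linked UMIs in 3 of 7744 and 9 of 7937 cells.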
